A study of Mus musculus with 6 samples.

How the data were processed

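RNA was sequenced from 6 hippocampal libraries, 3 WT and 3 Dicer1-ifKO, each from the pooled RNA of 3 mice, so 9 mice per genotype entered these libraries; the series' design text states 12 mice per genotype. Per the labels' protocols, total RNA was extracted with TRI reagent, treated with DNase, tested for recombination by qRT-PCR and made into libraries with a stranded mRNA kit. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie2 2.0.5, TopHat2 2.0.6, SAMtools 0.1.18 and DESeq2 were used with the builds GRCm38 and mm10. The read counter, the annotation release, the strand setting and any filter are not given in the sources used here. Replicates of a genotype are stated to be biological, each from other mice.

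Each deposited file lists 76938 transcripts with coordinates and 2 values, per the file headers a raw count and a normalised count. The deposited raw counts are whole reads per transcript, and reads in exons that several transcripts share were counted for each of them: in 3669 of 8458 genes with at least 2 transcripts of mean count 50 or more, 2 transcripts had counts within 1% of each other in all libraries. The deposited normalised values (unit signal) equal the count divided by 1 factor per library, 0.72, 0.994 and 1.01 for WT and 0.967, 1.13 and 1.28 for Dicer1-ifKO, and were not tested here. The design had assumed counts per gene. Since a sum over transcripts would count reads repeatedly, each gene symbol was represented by its transcript with the highest mean count over all 6 libraries, and the sum over transcripts and the test of all transcripts were run as alternatives chosen after seeing the files. Of 25896 symbols 22441 had a count. Coordinates are those of the files (GRCm38); 84.2% of the transcripts had identical coordinates in GENCODE release M21, from which transcript, coding and 3′ UTR sequences were taken.

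Counts summed over the representative transcripts ranged from 11832794 to 20677845 per library. Genes of the mitochondrial chromosome took 8.47% to 9.99% of these. A count of 3 corresponded to 0.145 to 0.254 CPM. Within a genotype, chi-square per degree of freedom between pairs of libraries was 1.75 to 4.31, so that no pair agreed within sampling noise and each library counted as 1 replicate. The common biological coefficient of variation was 0.0464. The strand of the reads was checked in 44 genes whose exons lie at least 90% inside exons of a gene on the other strand with a mean count of 500 or more: their count density had a median ratio of 2.00 to that gene, and 84.1% had a ratio of 0.5 or more. Reads of overlapping genes on opposite strands were therefore treated as not separable.

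Differences between Dicer1-ifKO and WT were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM normalization, filterByExpr with its minimum count of 10, genotype as the only term), with Benjamini-Hochberg adjustment over 17405 genes and a threshold of 0.05; log2 fold changes use edgeR's prior count of 0.125, and SE was taken from the fold change and its F statistic. CPM values are counts scaled to library size after TMM. Gene lists (32, fixed before the data were examined, as were the tests and the microRNA seeds) were tested with camera of limma 3.58.1 at the preset correlation of 0.01 with Benjamini-Hochberg adjustment over lists, with the correlation estimated in each list and with fry as alternatives. Genes named in the text were Dicer1, Esr1 and Camk2a, the 12 highest and 12 lowest log2 fold changes among genes at an adjusted p below 0.05 with a mean log2 CPM of at least 1 and no overlap between the 3 values of each group (predicted or unnamed models stayed in counts but were not named by this rule), and up to 4 members with the smallest p in each list described. Not every gene under this rule is described. Of 28 called genes, 28 met the level and overlap criteria and 4 were predicted models.

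For microRNA seeds, 15012 tested genes with an annotated 3′ UTR of at least 50 nt entered a linear model of the log2 fold change on the presence of a 7-mer site, with log2 UTR length, UTR GC content and mean log2 CPM as covariates. Each of 37 seeds (26 of brain microRNAs, 5 of other brain cells, 6 of other tissues) was ranked against up to 1000 random 7-mers with the same number of G or C and within 20% of its number of genes with a site, and class medians against 10000 random sets. Genes are not independent replicates, so these p describe the seeds relative to other 7-mers.

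The tests were tried on simulated data. In 10 simulations of the comparison of Dicer1-ifKO with WT, each with 200 of 17405 genes changed, the edgeR step recovered 52.8% of genes changed 1.25-fold, 76.6% at 1.5-fold, 93.3% at 2-fold and 100% at 4-fold, and 4.9% of its calls were false; with no gene changed it made 0.1 calls per simulation. Camera called a list raised by 0.15 on the log2 scale in 100% of the simulations and 0 other lists. Genes were simulated independently of each other, so these values do not show how often camera calls lists whose genes vary together. The raise was also larger in size than the median of every list called in the data. The seed test over 15012 genes found a rise of 0.01 per site in 5 of 5 simulations and had p below 0.05 in 3 of 40 without a rise. That rise gave a mean excess over controls of 0.00943, against 0.00196 between the genotypes, so recovery of so small an excess was not tried. Real splits that mixed the genotypes, and so kept part of any difference between them, gave seed p of 0.003, 0.0057 and otherwise 0.0744 or more. The rate without a rise thus need not hold for differences between these libraries.

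Alternatives were DESeq2 1.42.0 size factors, no normalization factors, no filter on low counts, a mean count of 50 or more, the DESeq2 Wald test, limma voom, a replicate block, and leaving out each library, with for seeds a 6-mer or 8-mer site, sites in the coding sequence, no covariates and a minimum mean log2 CPM of 3. Chosen after seeing the data were an offset per library for spline trends in transcript length and GC content (available for 98.9% of genes), the lists without Arsi, Esr1 and Slc6a7, and, for seeds, length and GC of the transcript as covariates, counts summed over transcripts, and the filter on mean log2 CPM with each library left out. Small RNA libraries were not analysed here.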

Results

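Messenger RNA was measured by sequencing in the hippocampus of adult male C57BL/6 mice that carried floxed alleles of Dicer1, the gene of the ribonuclease that cuts microRNA precursors into mature microRNAs. Dicer1-ifKO mice also carried CaMKIIa-creERT2, a Cre recombinase fused to an estrogen receptor domain and driven by a promoter of forebrain excitatory neurons, whereas WT mice carried no Cre. All mice were given tamoxifen, which activates the recombinase, and were killed 3 weeks later at 3 months of age. Each genotype had 3 libraries, each made from the pooled RNA of 3 mice. Counts over 1 representative transcript per gene summed to 11832794, 15826348 and 16125481 in WT replicates 1, 2 and 3, and to 15409074, 18008734 and 20677845 in Dicer1-ifKO replicates 1, 2 and 3. The design asks which hippocampal mRNAs differ once Dicer1 has been removed from adult forebrain neurons. As WT mice carried no Cre, it cannot separate the loss of Dicer1 from effects of the transgene and its active recombinase.

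Dicer1 mRNA itself did not differ detectably between the genotypes. Dicer1 (chromosome 12, 104687742 to 104751952, GRCm38) had counts of 653, 985 and 908 in WT replicates 1, 2 and 3 and of 896, 1134 and 1187 in Dicer1-ifKO replicates 1, 2 and 3, or 57.8 ± 3.63 (SD, n = 3) CPM (counts scaled to library size) in WT and 59.7 ± 2.82 (SD, n = 3) in Dicer1-ifKO. The log2 fold change was 0.04 (SE 0.06), with an adjusted p of 0.849 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The deposited table holds 1 Dicer1 transcript that spans the whole gene, so counts of the floxed exons could not be separated from those of the rest and the value does not check the deletion. Cells without the recombinase also contribute Dicer1 reads.

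Esr1, whose sequence is shared with the recombinase, and genes on both sides of Camk2a, whose promoter drives it, were higher in every Dicer1-ifKO library. Esr1, the estrogen receptor alpha gene (chromosome 10, 4611989 to 5005614), rose from 4.02 ± 0.76 (SD, n = 3) to 11.9 ± 1.76 (SD, n = 3) CPM, a log2 fold change of 1.58 (SE 0.15, adjusted p 7.53e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its transcripts that hold only the 3′ part of the gene carried the rise: Esr1-006, which starts at 4936526, had 49 counts over the WT libraries and 516 over the Dicer1-ifKO libraries (log2 fold change 3.08, SE 0.19). Esr1-007, which ends at 4967336, had 44 and 57 counts (log2 fold change 0.06, SE 0.32). Arsi, a sulfatase gene (chromosome 18, 60911780 to 60918561), rose from 18, 12 and 13 counts in WT to 85, 100 and 104 in Dicer1-ifKO, a log2 fold change of 2.44 (SE 0.22, adjusted p 7.53e-06, same test). Slc6a7, the brain proline transporter gene (60995381 to 61014199), rose by 0.42 on the log2 scale (SE 0.05, adjusted p 0.00022, same test). Camk2a lies between Arsi and Slc6a7, at 60925618 to 60988152, and had a log2 fold change of 0.11 (SE 0.05) that did not pass the test (adjusted p 0.42, edgeR with Benjamini-Hochberg adjustment). Its values were nevertheless higher in every Dicer1-ifKO library, at 3497 to 3713 CPM against 3279 to 3394 in WT. Groups did not overlap in 16.1% of all tested genes. Its other transcripts, which share reads, had 0.14 to 0.20, and none passed (lowest adjusted p 0.22, same test over transcripts).

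**Figure D1:**
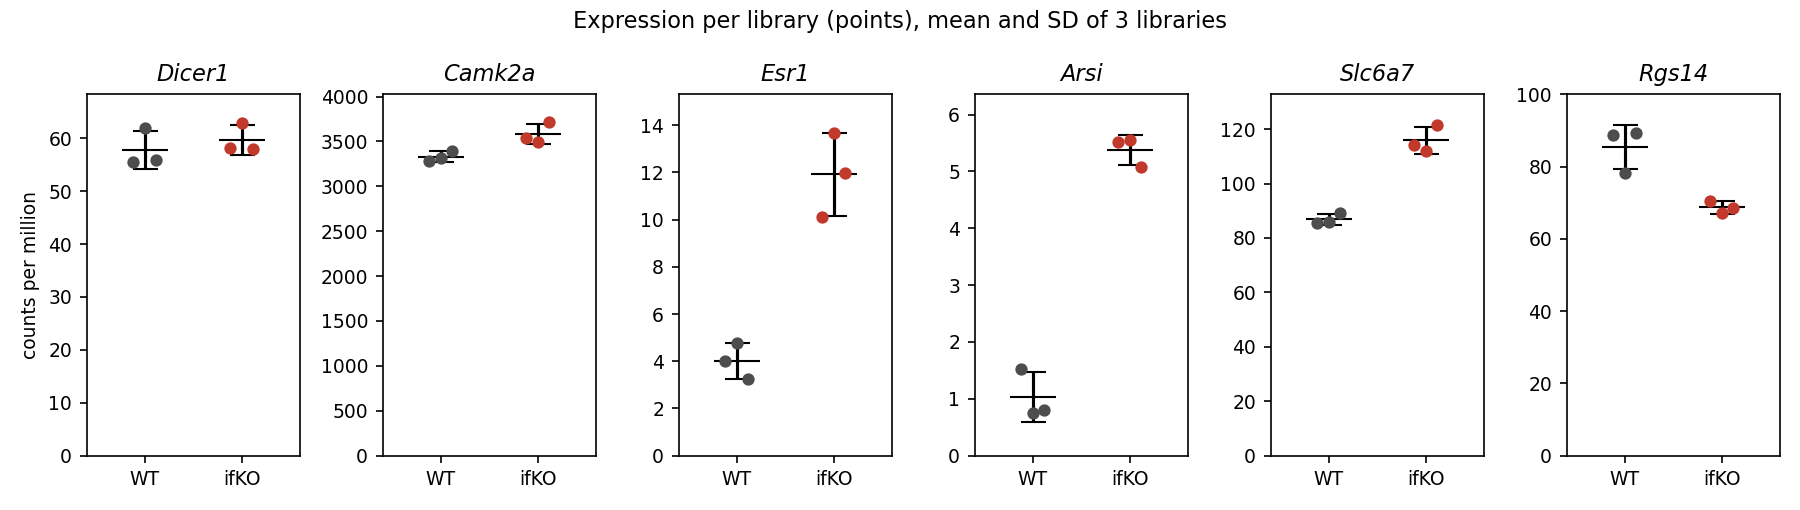
CPM (vertical axes, from 0) of Dicer1, Camk2a, Esr1, Arsi, Slc6a7 and Rgs14 in each library, with WT in grey and Dicer1-ifKO (ifKO) in red; points are libraries, and bars give the mean and SD of 3 libraries. Esr1, Arsi and Slc6a7 were higher in all Dicer1-ifKO libraries, as was Camk2a by less, Rgs14 was lower, and the Dicer1 values overlapped.

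**Figure D2:**
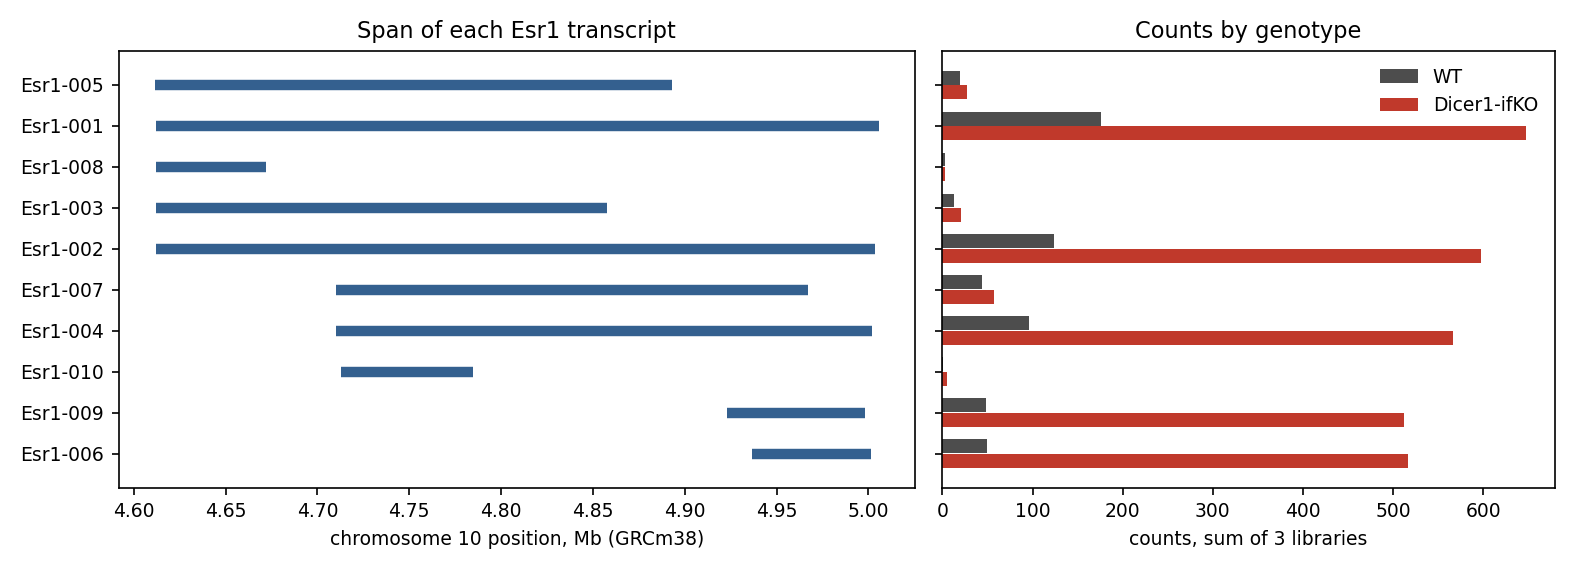
Span of each annotated Esr1 transcript on chromosome 10 (left, position in Mb) and its counts summed over the 3 libraries of each genotype (right, WT grey, Dicer1-ifKO red). Reads in exons that transcripts share were counted for each of them; Esr1-006 had 49 counts in WT and 516 in Dicer1-ifKO, and Esr1-007 had 44 and 57.

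Among 11 tested genes of the list fixed around Camk2a, 2 rose over all genes tested and 3 adjusted over the list alone, the additional one being Ndst1 (log2 fold change 0.21, SE 0.05, adjusted p 0.141 over all genes in edgeR with Benjamini-Hochberg adjustment). The list stood above other genes in camera with the preset correlation (adjusted p 4.16e-09), and had an adjusted p = 0.0988 with an estimated correlation. Without Arsi, Esr1 and Slc6a7 the camera adjusted p was 0.0567. The 26 tested genes that lie within 1 Mb beyond Arsi and Slc6a7 had a median log2 fold change of 0.02 and none passed the edgeR test.

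**Figure D3:**
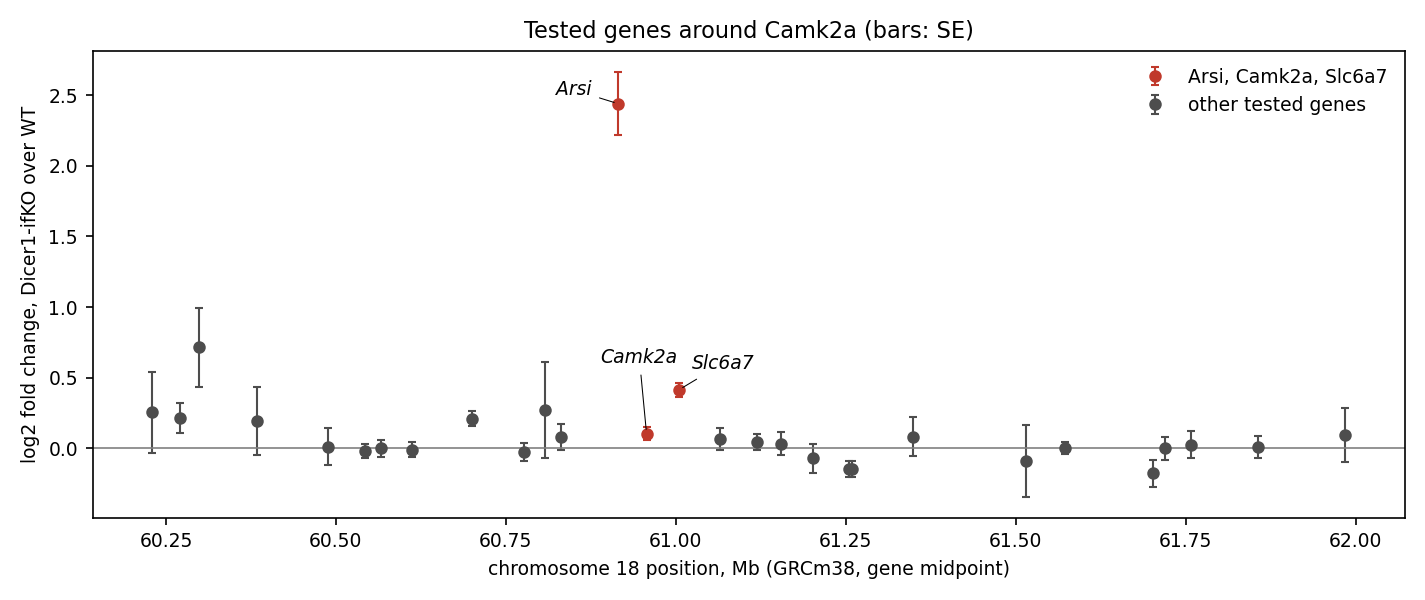
Log2 fold change of Dicer1-ifKO over WT (vertical axis, bars are SE) against the midpoint of each tested gene around Camk2a on chromosome 18 (horizontal axis, Mb). Arsi stood at 2.44, Slc6a7 at 0.42 and Camk2a at 0.11, and the genes beyond them had a median of 0.02.

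Across the transcriptome few genes differed, and most of those were modestly higher in Dicer1-ifKO. Of 17405 genes tested, 22 rose and 6 fell at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1815 had an unadjusted p below 0.05. Prkaa2, a catalytic subunit of AMP-activated protein kinase, rose by 0.39 on the log2 scale (SE 0.07), Traf3, a TNF receptor-associated adaptor, by 0.34 (SE 0.05), Unc5a, a netrin receptor, by 0.34 (SE 0.06), and Panx2, a pannexin, by 0.31 (SE 0.05). Raver2, an RNA-binding protein gene, rose by 0.36 (SE 0.06), Sbk1, a kinase gene, by 0.32 (SE 0.05) and Ankrd52, an ankyrin repeat protein gene, by 0.32 (SE 0.05). Adjusted p for these 7 genes lay between 0.00355 and 0.0173 in the edgeR test. Tcte3 had a log2 fold change of 0.59 (SE 0.12, adjusted p 0.0349, edgeR with Benjamini-Hochberg adjustment), but its counts were nearly equal to those of its neighbouring copy Gm3448, which was also called at 0.60 (SE 0.11), and shared exon sequence with 2210404J11Rik on the other strand, so the source of these reads is uncertain.

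Among the genes that fell, Rgs14, a regulator of G-protein signalling that is abundant in CA2 pyramidal neurons, was lower by 0.31 on the log2 scale (SE 0.06), from 85.4 ± 6.13 to 68.7 ± 1.74 CPM (SD, n = 3 libraries each). Calb1, the calcium-binding protein calbindin of dentate granule cells, fell by 0.27 (SE 0.05), from 131 ± 3.88 to 109 ± 6.87 CPM. Map2k1, the kinase MEK1 of the ERK pathway, fell by 0.25 (SE 0.05), Eif2s1, the alpha subunit of translation initiation factor eIF2, by 0.31 (SE 0.06) and Stra6, a receptor for retinol-binding protein, by 0.55 (SE 0.10). Adjusted p for these 5 genes lay between 0.0173 and 0.0452 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In 2797 of the tested genes, 16.1%, the 3 values of one genotype did not overlap the 3 of the other, where chance gives 10%. The number called was 18, 105 and 14 without WT replicates 1, 2 and 3, and 6, 18 and 26 without Dicer1-ifKO replicates 1, 2 and 3. Genes called in all 6 of these fits were 6 in number: Arsi, Esr1, Slc6a7, Ankrd52 and the predicted transcripts 1700020I14Rik and Gm17201, the last of which shares 59.5% of its exons with Ankrd52 on the opposite strand, so that its reads cannot be told from those of Ankrd52.

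**Figure D4:**
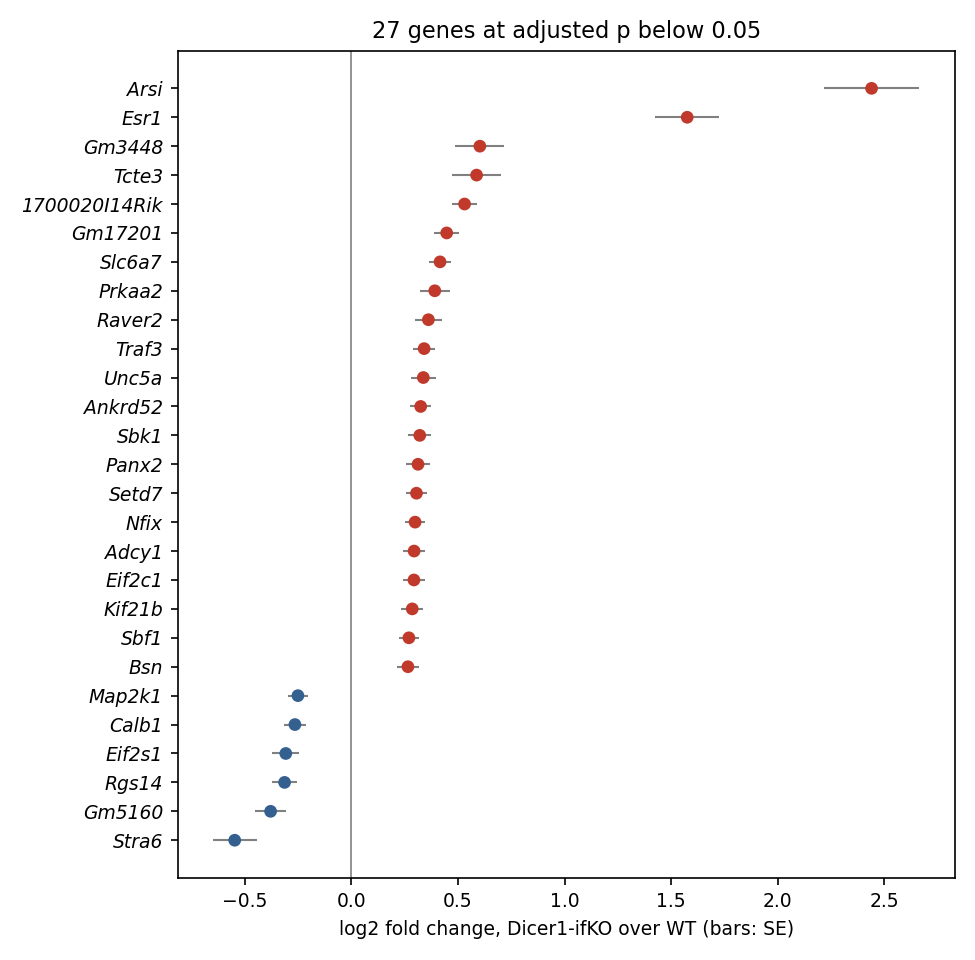
Log2 fold change of Dicer1-ifKO over WT (horizontal axis, bars are SE) of 27 of the 28 genes at an adjusted p below 0.05, sorted by size, with higher genes in red and lower genes in blue. Arsi (2.44) and Esr1 (1.58) stood apart from the others, which lay between -0.55 and 0.60.

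Voltage-gated channel and glutamate receptor genes stood slightly higher in Dicer1-ifKO as groups. Single members did not pass over all genes in the edgeR test with filterByExpr and all libraries. Of 26 tested sodium and calcium channel genes, 24 had a positive log2 fold change, with a median of 0.09; Cacna1g, a T-type calcium channel gene, had 0.23 (SE 0.06) and Scn8a, a sodium channel gene, 0.14 (SE 0.05). No member passed over all genes and 1 was higher adjusted over the list alone. The list was called by camera with the preset correlation (adjusted p 3.27e-06), with an adjusted p = 0.493 with an estimated correlation. Of 41 potassium and HCN channel genes, 30 were positive (median 0.06, but 0.04 without Dicer1-ifKO replicate 2), 0 passed over all genes and 2 adjusted over the list alone. Hcn2, a hyperpolarization-activated channel gene, had 0.21 (SE 0.05). Of 22 glutamate receptor genes, 19 were positive (median 0.06, but 0.12 without Dicer1-ifKO replicate 3 and 0.10 without WT replicate 2), with 0 passing over all genes or adjusted over the list alone; Grik3 had 0.18 (SE 0.06) and Grin2c 0.16 (SE 0.06). Both lists were called by camera (adjusted p 0.00218 each), with an adjusted p = 0.493 with an estimated correlation for each. GABA receptor genes were not called (14 tested, median 0.03, camera adjusted p 0.18).

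Sterol synthesis genes stood lower in Dicer1-ifKO. Of 18 tested members, 17 had a negative log2 fold change and the median was -0.13 (-0.08 without Dicer1-ifKO replicate 3, with a camera adjusted p of 0.00451). Sqle, squalene epoxidase, had -0.28 (SE 0.06), Sc4mol, a sterol methyl oxidase, -0.21 (SE 0.06), Fdft1, squalene synthase, -0.21 (SE 0.06) and Hmgcs1, HMG-CoA synthase, -0.15 (SE 0.06). None passed over all genes, and 3 were lower adjusted over the list alone. Camera called the list with the preset correlation (adjusted p 6.1e-06), with an adjusted p = 0.493 with an estimated correlation. Genes of mitochondrial oxidative phosphorylation had a smaller shift, with 18 of 25 negative and a median of -0.03 (-0.06 without WT replicate 2). Cycs, cytochrome c, had -0.20 (SE 0.05) and Ndufa1, a complex I subunit, -0.30 (SE 0.08), and 2 members were lower adjusted over the list alone (0 over all genes). That list was called at an adjusted p of 0.0278, with an adjusted p = 0.574 with an estimated correlation.

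Libraries also differed along transcript length. Across 11963 genes, which are not independent replicates, the log2 fold change correlated with transcript length (Spearman's rho 0.329), and WT replicate 1, the shallowest library, had the deviations most correlated with length (rho -0.432). That library also stood apart on the first principal component, at -26.6 against 1.5 to 10.1 for the others (30.4% of the variance). On the second (19.3%), the Dicer1-ifKO libraries lay at 5.73 to 9.98 and the WT libraries at -17.4 to 2.58. Without WT replicate 1, rho was 0.172, and the sterol list (camera adjusted p 4.63e-05) and the sodium and calcium channel list (0.00313, median 0.05 against 0.09) were called while the potassium channel (0.117, median 0.03 against 0.06), glutamate receptor (0.0503) and oxidative phosphorylation (0.164, median -0.02 against -0.03) lists were not. The glutamate receptor median did not shrink (0.07 against 0.06). Deviations correlated with length at rho 0.209, 0.287 and 0.093 in Dicer1-ifKO replicates 1, 2 and 3. In WT replicates 2 and 3 rho was 0.147 and -0.166. The trend thus partly followed genotype, and removing it may also remove part of a genotype difference. With an offset for length and GC content in each library, chosen after seeing the data, the same 2 of these 5 lists were called, at 2.33e-06 for sterol synthesis and 0.0092 for sodium and calcium channels, whose median was 0.04; with both changes the channel list was not (0.16) and the sterol list was (3.14e-05). Without Dicer1-ifKO replicate 2 the glutamate receptor (0.1249) and oxidative phosphorylation (0.135) lists were not called, and the latter was not without WT replicate 3 (0.1247).

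Genes of the microRNA machinery and microRNA hosts stood slightly higher, in part along the trend with transcript length. Eif2c1, which encodes the Argonaute protein AGO1, rose by 0.29 on the log2 scale (SE 0.05, adjusted p 0.0162, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and was the only member of 19 tested microRNA pathway genes that passed over all genes; 4 were higher and 1 lower adjusted over the list alone. Tnrc6c, a GW182 protein gene, had 0.17 (SE 0.05). Camera called this list (adjusted p 0.0174), with an adjusted p = 0.576 with an estimated correlation. Of 4 tested non-coding microRNA host genes, C130071C03Rik, a host of miR-9, had 0.22 (SE 0.05). Meg3, the imprinted transcript beside a microRNA cluster, had 0.19 (SE 0.06). The others were positive by far less than their SE, 2810008D09Rik at 0.01 (SE 0.11) and A930005H10Rik at 0.01 (SE 0.29). The list had 0 members passing over all genes and 2 higher adjusted over the list alone (camera adjusted p 0.0159, and adjusted p = 0.493 with an estimated correlation). Of 27 protein-coding hosts, 19 were positive, 0 passed over all genes and 3 adjusted over the list alone, with Ctdsp2 at 0.18 (SE 0.05) and Arpp21 at 0.20 (SE 0.06) (camera adjusted p 0.0441, and adjusted p = 0.493 with an estimated correlation). Genes of the ATF4 and integrated stress response were slightly lower, with 14 of 18 negative, a median of -0.05, Asns at -0.16 (SE 0.05) and Atf4 at -0.15 (SE 0.06); 0 passed over all genes and 2 adjusted over the list alone (camera adjusted p 0.0286, and adjusted p = 0.493 with an estimated correlation). Without WT replicate 1 camera called none of these 4 lists, at adjusted p of 0.265, 0.122, 0.132 and 0.0946, though the medians shrank for the pathway (0.02 against 0.04) and protein-coding host lists (0.03 against 0.06) and not for the stress response (-0.05 in both, but -0.02 without Dicer1-ifKO replicate 2 and -0.08 without Dicer1-ifKO replicate 1); among the non-coding hosts, of which 5 were then tested, Meg3 had 0.14 and C130071C03Rik 0.21. With the length and GC offset the pathway (0.208, median 0.02) and protein-coding host (0.273, median 0.01) lists were not called. Without a filter on low counts 7 non-coding hosts were tested, with a median of 0.03 and no call (0.0867). The protein-coding hosts and the stress response list were also not called without WT replicate 3 (0.0727 and 0.0873) or Dicer1-ifKO replicate 2 (0.135 and 0.153), nor the former without Dicer1-ifKO replicate 3 (0.0535). The protein-coding host median was also 0.03 without Dicer1-ifKO replicate 2, and the pathway median was 0.07 without WT replicate 2.

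Markers of cell types and of injury were not called as groups with all libraries, but several depended on single libraries. Camera adjusted p was 0.827 for excitatory pyramidal neuron markers (20 tested, median log2 fold change 0.00), 0.18 for dentate granule cell markers (12, -0.05), 0.502 for inhibitory neuron markers (18, 0.04), 0.999 for astrocyte markers (17, 0.01), 0.709 for reactive astrocyte genes (13, -0.02), 0.133 for microglia markers (19, -0.07), 0.432 for interferon response genes (19, -0.08), 0.273 for oligodendrocyte markers (16, -0.04), 0.999 for their precursors (9, -0.02), 0.586 for endothelial (14, 0.03), 0.502 for mural (9, 0.07) and 0.174 for choroid plexus markers (9, -0.14). Adjusted over the list alone, 2 astrocyte markers were lower and none of the microglia, oligodendrocyte or pyramidal markers passed. Among dentate markers Calb1 fell, while Plk5 had 0.31 (SE 0.08), which passed only adjusted over the list alone. The dentate markers differed in either direction by fry's mixed test (adjusted p 0.0044), which does not compare them with other genes. Markers of thalamus and striatum (0.174; 13, 0.10) and erythrocyte genes (0.18; 5, 0.11), which would mark a difference in dissection or blood, were not called with all libraries. Erythrocyte genes were called as higher without WT replicate 1 (camera adjusted p 0.00053, median 0.26) and Dicer1-ifKO replicate 1 (0.0155), and without WT replicate 1 with the length and GC offset (0.000109). Thalamus and striatum markers were called as higher without Dicer1-ifKO replicate 3 (0.0222). Oligodendrocyte markers were called as lower without WT replicate 2 (0.000125, median -0.12) or Dicer1-ifKO replicate 1 (0.0107), dentate markers without WT replicate 2 (0.0378) or Dicer1-ifKO replicate 3 (0.0356), microglia markers without WT replicate 2 (0.02) and choroid plexus markers without Dicer1-ifKO replicate 1 (0.0495). The oligodendrocyte median was instead positive, and not called, without WT replicate 3 (0.03) and without Dicer1-ifKO replicate 3 (0.04). Without Dicer1-ifKO replicate 3 the choroid plexus median was 0.02. These calls used the preset correlation of 0.01. With all libraries the estimated correlation was 0.645 for erythrocyte genes and 0.748 for oligodendrocyte markers (camera adjusted p 0.74 and 0.844 with it). A difference in cell or tissue composition between the pools is therefore not shown and not excluded.

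Other responses fixed for the test were also not called with all libraries. Camera adjusted p was 0.673 for immediate early genes (30 tested, median log2 fold change -0.00), 0.609 for p53 target and apoptosis genes (20, -0.01), 0.166 for neuropeptide genes (17, -0.07; called as lower without WT replicate 2 at 0.041 and Dicer1-ifKO replicate 3 at 0.0222), 0.827 for adult neurogenesis genes (10, -0.01) and 0.827 for actin and extracellular matrix genes (27, 0.01). Published targets of miR-124 (27, -0.01) and let-7 (24, 0.02) had adjusted p of 0.609 and 0.273. The miR-124 targets differed in either direction by fry's mixed test (adjusted p 0.0115), which does not compare a list with other genes. Of the 27, 2 had an unadjusted p below 0.05 in edgeR, against 1815 of all 17405 genes tested. These were Ctdsp2, which was higher, and Efnb1, which was lower at -0.42 (SE 0.13). Over all genes 0 members of either target list passed, and adjusted over the list alone 1 miR-124 target, Ctdsp2, and 1 let-7 target, Ccnd2 at 0.31 (SE 0.06), were higher.

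**Figure D5:**
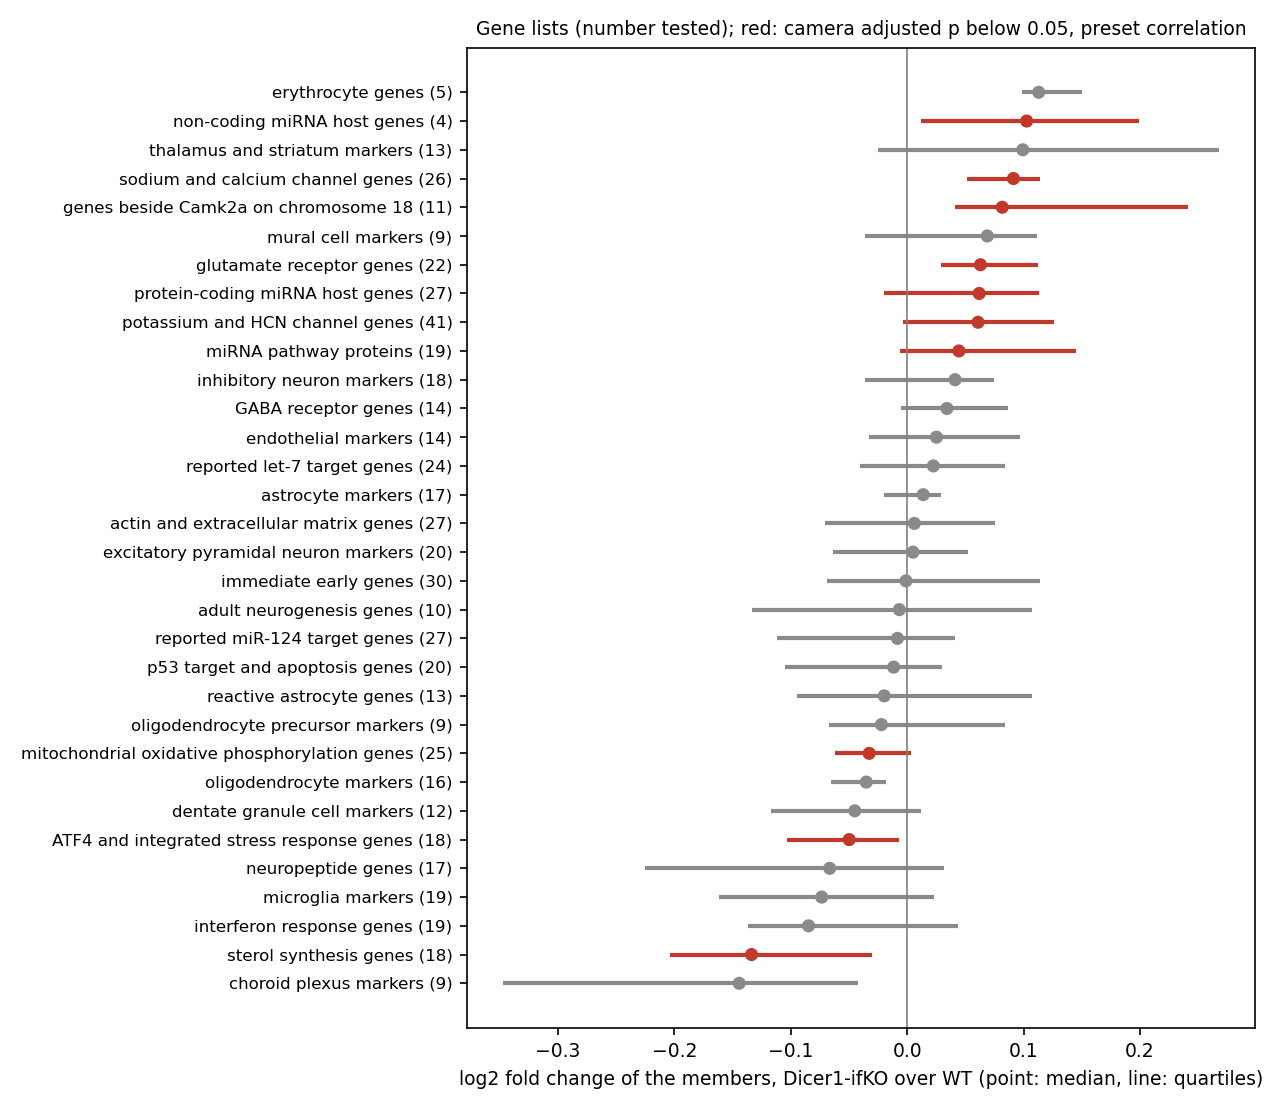
Median (point) and quartiles (line) of the log2 fold changes of Dicer1-ifKO over WT in each of the 32 gene lists, with the number of genes tested in parentheses; red marks camera adjusted p below 0.05 with the preset correlation. Sterol synthesis genes had a median of -0.13 and sodium and calcium channel genes of 0.09; with an estimated correlation 0 of the 32 lists were called.

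Because Dicer1 makes mature microRNAs, the fold changes were compared between mRNAs with and without microRNA seed sites in the 3′ UTR. Over all 15012 genes, sites of no single microRNA were associated with a detectable difference: 0 of 37 seeds passed against control 7-mers of like composition (Benjamini-Hochberg adjustment). When the test was limited to 10982 genes with a mean log2 CPM of 3 or more, 3 of the 37 had an adjusted p below 0.05. The 26 seeds of brain microRNAs had a median coefficient of 0.00589 on the log2 scale, against 0.00393 for control 7-mers (95% of random sets 0.00189 to 0.00593, p 0.0579). Their median was 0.00228 against 0.00158 without WT replicate 1, and 0.00405 against 0.00331 without Dicer1-ifKO replicate 2. The 5 seeds of microRNAs of other brain cells had a median of -0.00105 against 0.0032 (p 0.188). The smallest p were those of miR-219a-5p, of that class, with 0.0212 against 0.0028 for its control 7-mers, and of the brain seed miR-137-3p, with 0.0141 against 0.0015 (adjusted p 0.129 each over the 37 seeds, Benjamini-Hochberg); that of miR-124-3p had 0.0083 against 0.0044 (p 0.331). Among the more abundant genes the brain seeds had a median of 0.00741 against 0.00361 (p 0.0001, the smallest that 10000 random sets can give); the 3 seeds that passed were miR-137-3p, miR-25/92-3p and miR-9-5p. No seed passed there without WT replicate 1, nor, with all libraries, once transcript length and GC content were added as covariates. Leaving out 1 other library gave 1 to 4 passing seeds there. With the covariates 3 passed without WT replicate 3 and 0 without any other library. Seeds of microRNAs of other tissues had a median of 0.00418 against 0.00333 there (6 seeds, p 0.715). These p compare seeds with other 7-mers and not samples: among the 9 other splits of the 6 libraries, 2 had a larger excess over all genes than the genotypes. Each of these splits mixed the genotypes and so kept part of any difference between them.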

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

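The tests of Esr1 transcripts, of WT replicate 1, of the sterol list and of other splits of the libraries were chosen after the results were seen; those of the genes around Camk2a and of the length and GC trend over all 5 lists and over the seeds were set down before their outcomes.

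Transcripts other than the representative one were outside the gene-level comparison, and 2 of them were higher in Dicer1-ifKO than in WT while their gene was not called. Abca3-006 (chromosome 17, 24352085 to 24377842) had a log2 fold change of 0.52 (SE 0.09, adjusted p 0.021 over 60500 transcripts, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), against 0.15 (SE 0.06) for Abca3 as a gene. Ank1-009 (chromosome 8, 23096101 to 23123638) had 0.55 (SE 0.10, adjusted p 0.0317, same test), against 0.30 (SE 0.07) for Ank1. A further 2 such transcripts were lower: Gclm-003 at -0.36 (SE 0.06, adjusted p 0.0202, same test) and Rbm17-005 at -0.45 (SE 0.09, adjusted p 0.0486, same test). Groups of 3 libraries are too small for a test of single outlying samples.

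Esr1, Arsi and Slc6a7 rose together, and all relate to the recombinase transgene or to the gene whose promoter drives it. Reads of the estrogen receptor domain of CreERT2 may have been counted as Esr1: the log2 fold change of the 3′ transcript Esr1-006 exceeded that of Esr1-007, which ends inside the gene, by 3.01 (combined SE 0.37). A transgene that carries neighbours of Camk2a could account for Arsi and Slc6a7. The tested genes within 1 Mb beyond them had a median log2 fold change of 0.02 (95% bootstrap interval -0.00 to 0.08), so no rise common to the region was seen. Single genes on the Arsi side were higher without passing, such as Ndst1 at 0.21 (SE 0.05) and F830016B08Rik at 0.72 (SE 0.28). Closer to Arsi, Tcof1 had 0.08 (SE 0.09) and Rps14 -0.02 (SE 0.06). The median over both sides thus does not show where a rise ends. The median over all tested genes was -0.003, so a flanking median this low was likely under any local cause. It cannot tell a carried segment from another local effect on Arsi and Slc6a7. For Esr1 the values argue against a rise of the whole gene by 1.58, as Esr1-007 had 0.06 (SE 0.32), with few counts. Esr1-005 and Esr1-003, which also end early, went from 20 to 27 and from 13 to 21 counts in larger libraries. A smaller effect of the loss of Dicer1 on Esr1, or one on its 3′ part, stays open. An effect on Arsi and Slc6a7 stays open too, as every Dicer1-ifKO library carries the transgene. WT mice carried no Cre, so for all other genes, lists and seeds too, loss of Dicer1 cannot be told from effects of the transgene or the active recombinase.

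Channel and glutamate receptor lists stood higher, and sterol and oxidative phosphorylation lists lower, in Dicer1-ifKO. A trend with transcript length and GC content may account for a part: with it removed 2 of these 5 lists were called, and the medians of the lost lists shrank, to 0.02 for potassium channels (from 0.06), 0.02 for glutamate receptors (from 0.06) and -0.01 for oxidative phosphorylation (from -0.03). Without WT replicate 1 also 2 of the 5 were called, but the glutamate receptor median was 0.07, so whether that library is the source stays open. For sterol synthesis the tables argue against either as the whole cause, with a camera adjusted p of 2.33e-06 after removal of the trend (median log2 fold change -0.13 before and after) and of 4.63e-05 without that library, both at the preset correlation; with all libraries and no offset the list had an adjusted p = 0.493 with an estimated correlation. The genotypes gave 10 lists and the highest of the 9 other splits also 10 (2 of the 10 splits as large), too few splits for a share under 0.05. The lowest camera adjusted p among other splits was 0.000172 for sterol synthesis (6.1e-06 for the genotypes, called in 4 of the 9). For sodium and calcium channels it was 0.000351 (3.27e-06, called in 6). It was 0.0024 for potassium channels (0.00218), 0.000278 for glutamate receptors (0.00218) and 0.005 for oxidative phosphorylation (0.0278). Each other split grouped 2 libraries of 1 genotype with 1 of the other, so it kept part of any genotype difference. A call in such a split thus does not by itself show other structure. Structure among the libraries besides genotype stays open, as does an effect of Dicer1.

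Brain microRNA seed sites went with slightly higher expression in Dicer1-ifKO among abundant genes. Among those genes a trend with transcript length and GC content, as modelled, did not remove the excess over control 7-mers. With both as covariates it was 0.00309 with a p of 0.0001, the smallest the random sets can give. The median coefficient there was 0.0028, but 0.0048 without WT replicate 2 and 0.0046 without Dicer1-ifKO replicate 3. Over all genes, without these covariates, the excess was 0.00196 and was not past the threshold. Of the 10 splits, the genotypes included, 3 had one as large (highest other 0.00283), in a design where no share under 0.05 is possible. With the covariates, over all genes, the median was 0.00025 against -0.00034 for control 7-mers (p 0.571 against random sets), so a trend as the cause stays open there. With the covariates, among abundant genes, the other splits, which keep part of any genotype difference, reached 0.00259 (p 0.0002 against random sets). Relief from microRNA repression may thus contribute but cannot be told apart from differences between the libraries.

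The genotypes gave 28 called genes and the highest of the 9 other splits gave 11, so 1 of the 10 splits had a count as large; 10 splits are too few for a share under 0.05.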

How the results depend on the processing

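Settings that added an offset for length and GC content, summed transcripts, tested all transcripts, or combined the abundance filter of the seed test with other changes were chosen after the data were seen. The count of 28 genes stayed within 1.5 times under DESeq2 size factors (29), no normalization factors (28), a mean count of 50 or more (28) and limma voom (28), and was 38 with the offset (26 shared), 23 with the offset and without WT replicate 1, and 27 genes when all transcripts were tested. Without a filter on low counts 151 genes were called, including all 28; the DESeq2 Wald test called 80, of which 19 were shared, with 13497 genes given no adjusted p; and counts summed over transcripts gave 7. Among the called genes named by the rule, 11 had an adjusted p in the Wald test, and all 11 kept their call. Part of the difference from the Wald test thus lies in genes left without an adjusted p. Among 33 other named list members, the call changed in 10 without the filter and in 6 of 25 in the Wald test. The causes of these differences were not tested further. Leaving out 1 library gave 6 to 105 genes, and no called gene changed sign. Dicer1 stayed between 0.01 and 0.10 on the log2 scale without 1 library, and Esr1 stayed between 1.43 and 1.74. Among the settings chosen before the data were seen, Dicer1 never passed. Esr1 passed in all of these but the DESeq2 Wald test, which gave neither gene an adjusted p. Of 10 lists called, 0 held with an estimated correlation, 0 with fry, 5 with the offset and 2 with the offset and without WT replicate 1, where 3 lists in all were called; leaving out 1 library gave 4 to 14 lists. The seed result (p 0.0579) passed with 6-mers (0.0034, where seeds of other tissues passed too, at 0.0371), 8-mers (0.0017), abundant genes (0.0001, the smallest possible), and abundant genes with length and GC covariates (0.0001), and not with sites in the coding sequence (0.0866), no covariates (0.231), length and GC covariates over all genes (0.571) or summed transcripts (0.313). Leaving out 1 library gave a seed p of 0.0263 to 0.531 over all genes, 0.0001 to 0.0013 over abundant genes (0.0002 without WT replicate 1 and 0.0009 without Dicer1-ifKO replicate 1) and 0.0001 to 0.0002 with the covariates added. With the replicate number as a block, 22 genes (21 of them shared with the 28) and 10 lists were called, and the seed p was 0.0449. Tcte3, Stra6, Eif2s1, Calb1 and Bsn were among the genes that lost their call. The correlations of deviations between samples of equal number were -0.07, 0.03 and -0.09, and those of unequal number lay between -0.06 and 0.13. No pairing by number was seen, but so few correlations cannot exclude a shared litter, day or batch.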

Other observations

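The test of CA2 markers was set down before its outcome was seen; the genes of the opening paragraph were named after their values were seen.

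Further genes were called outside the rule for named genes. Adcy1, a calcium-stimulated adenylyl cyclase, rose by 0.29 on the log2 scale (SE 0.05), from 886 ± 71.4 to 1086 ± 5.57 CPM (SD, n = 3 libraries each), and Bsn, the presynaptic scaffold bassoon, by 0.26 (SE 0.05). Kif21b, a kinesin, rose by 0.29 (SE 0.05), Sbf1, a myotubularin-related protein, by 0.27 (SE 0.05), Setd7, a lysine methyltransferase, by 0.31 (SE 0.05) and Nfix, a nuclear factor I transcription factor, by 0.30 (SE 0.05), with a short exon overlap with G430095P16Rik on the other strand. The long non-coding RNA 1700020I14Rik (chromosome 2, 119594303 to 119607502) rose from 359 ± 35.4 to 520 ± 27.8 CPM, a log2 fold change of 0.53 (SE 0.06, adjusted p 6.6e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and was called in each of the 6 fits that left out a library.

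Because Rgs14 is abundant in CA2 neurons, its fall may reflect lower expression of CA2 genes in general. A general fall of that size was not borne out: 9 tested CA2 markers other than Rgs14 had a median log2 fold change of -0.04 (quartiles -0.16 and 0.11), against -0.31 for Rgs14, and a camera p of 0.555. Hippocampal RNA mixes CA2 with other cells, so a marker that is also expressed elsewhere need not follow CA2. A smaller fall in CA2 is not excluded. Of the 9, 5 were lower and 4 higher; Pcp4 had -0.16 (SE 0.06) and Map3k15 -0.16 (SE 0.05), while Acan had 0.37 (SE 0.16), and none of the 3, which were named after their values were seen, passed over all genes.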
